A study of Mus musculus with 8 samples.

How the data were processed

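Poly(A) RNA of dorsal root ganglia of levels L3-L5 was sequenced from 2 groups of mice with a joint injection of monosodium iodoacetate, which is used to model osteoarthritis: MIA, with no further treatment, and MIA_Acu, with daily manual acupuncture. Libraries were made with the NEBNext Ultra RNA kit after TRIzol extraction, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic and the mouse build GRCm39 (mm39). The aligner, the counter, its strand setting, the annotation release and the tool versions are not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies may have been split or shared in ways that cannot be checked. Poly(A) selection leaves unpolyadenylated RNA out of the measurement. The deposited values are raw counts per Ensembl gene in 1 table of 54532 rows, with the authors' gene symbols beside the identifiers; all values are whole numbers, and 20427 rows hold no count in any library. Of the rows, 207 share a symbol with another row and 27 carry symbols turned into dates, none of them in a list used here. No coordinates are given, since the annotation at hand is of another build (GRCm38); its transcripts were used only for transcript length and GC content, which 18956 of the tested genes (99.9%) have.

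Each column was given its group from its name. Of the 8 columns, 6 carry a number that matches a sample title of the same group (1, 2 and 5 in each). The MIA column numbered 4 and the MIA_Acu column numbered 3 match no title, since the titles give MIA a number 3 and MIA_Acu a number 4. Both were used as replicates of the group in their name, and whether they were exchanged is open; tests were therefore also run on the 6 matched libraries alone and with the groups of these 2 columns exchanged. The submitters describe 3 groups of 3 mice and name 2 of them; 2 groups of 4 libraries were analysed here. The labels do not tie each library to its own animal, so p-values measure the spread between libraries. Libraries of a group differed by more than sampling noise in each pair: the chi-square statistic of their counts per degree of freedom was 19.58 or more, which argues only against copies of 1 library.

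Library totals were 32892804 to 40627041 counts. At the gene level, changes between groups were tested with edgeR 4.0.16 (quasi-likelihood test, glmQLFit and glmQLFTest) in R 4.3.3, after filterByExpr by group (minimum count 10, minimum total 15) and TMM normalization, with group as the only term and Benjamini-Hochberg adjustment; the threshold was an adjusted p under 0.05. The biological coefficient of variation was 22.9%. Standard errors of log2 fold changes were derived from the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. A total of 48 gene lists, with 708 distinct tested genes, covered the cell types of the ganglion, tissues and blood cells that dissection can add, and pathways of pain, inflammation and acupuncture. They were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives except those said to be added. The lists were tested with limma 3.58.1 camera (preset correlation 0.01, two-sided) on log2 CPM, with Benjamini-Hochberg adjustment over the lists; camera compares a list with all other tested genes. A list score is the mean log2 CPM of its members, centred on the mean of the 8 libraries. For each list, the number of members past the threshold adjusted over the list alone was counted beside the number adjusted over all genes.

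The rule for named genes took, where 12 or more genes passed in a direction, the 12 with the largest log2 fold change with a symbol not of predicted form and a mean log2 CPM of at least 1; otherwise all that passed and the smallest p-values up to 6 in each direction, written as not past the threshold. It added members of lists past the threshold, up to 6 a list, or else the 2 members with the smallest p of each called list, and 20 genes of pain, inflammation and nerve injury with their values in any case. Its first part was also applied to the fit of the 6 matched libraries, a choice made after seeing the data. Some genes that the rule names are not reported here, and their places were not filled. Members named outside the rule are marked as such.

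Alternatives were DESeq2 size factors in the same fit, no filter on low counts (at least 1 count in all), a stricter filter (10 counts in 4 libraries and mean log2 CPM of 1), each library left out in turn, the 6 libraries numbered 1, 2 and 5 with and without the replicate number as a block, DESeq2 1.42.0, limma voom with and without sample weights, camera with an estimated correlation or on ranks, and fry. Added after seeing the data were the exchange of the libraries numbered 3 and 4, the omission of each of 16 pairs of libraries, and removal of the trend of each library on transcript length and GC.

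The gene test was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes. With 8 libraries and 18641 genes, it recovered 58% of 100 genes changed 2-fold and 85% of 100 changed 4-fold, with 11 unchanged genes called. With 6 libraries and 18616 genes, the shares were 48% and 76%, with 11 unchanged genes called. In a simulation of 8 libraries, camera called the 1 list shifted by 0.5 on the log2 scale and none of the other 47. Simulated genes were drawn independently of each other, whereas members of real lists vary together. The estimated correlation was 0.71 in the pan-neuronal and 0.96 in the myelinating Schwann list. The simulation therefore does not show how often camera calls unchanged lists in these data.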

Results

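Dorsal root ganglia hold the cell bodies of the sensory neurons that supply the limb, among satellite glia, Schwann cells, vessels and resident immune cells. RNA of L3-L5 ganglia was measured in C57BL/6 mice whose joint disease was induced with monosodium iodoacetate, an inhibitor of glycolysis that damages cartilage. The MIA group (4 libraries) had no further treatment, and the MIA_Acu group (4 libraries) received manual acupuncture at ST36, a point below the knee, daily for 7 days. The comparison asked which transcripts of the ganglion, above all those of neuro-immune signalling, differ after acupuncture. Uninjured ganglia were not analysed here, so no value says how far either group lies from the healthy state. No group with sham needling or handling alone was analysed either, so acupuncture cannot be told apart from the handling that goes with it. Total counts of the MIA libraries numbered 1, 2, 4 and 5 were 32892804, 38125577, 37673228 and 40627041, and those of the MIA_Acu libraries numbered 1, 2, 3 and 5 were 36499861, 35440711, 35965737 and 36807864. Between 24754 and 26755 genes had a count. Transcripts of Y-linked genes were present in each library and Xist was at most 0.712 CPM.

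On average over the libraries of a group, transcripts of sensory neurons took a lower share of the RNA of MIA_Acu ganglia than of MIA ganglia. Those of myelinating Schwann cells, blood vessels, connective tissue and macrophages took a higher share. Of 48 gene lists, 24 differed between the groups in camera. The 9 that fell were 5 lists of neuron types and those of ion channels, neurotrophic factors, nerve injury genes and synaptic vesicle release. The 15 that rose included myelinating Schwann, endothelial, mural, fibroblast and macrophage markers and extracellular matrix genes. No list was called with an estimated correlation in place of the preset one, with adjusted p = 0.413 at the lowest, and fry called 6, of which 5 are among the 24. Each of the 35 splits of the 8 libraries into 2 groups of 4 called lists too, from 8 to 26. A camera call alone therefore does not exclude chance.

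Single genes did not pass the threshold in all 8 libraries: edgeR called 0 of 18971 genes (smallest adjusted p = 0.0881), while 4137 had an unadjusted p under 0.05 (2123 higher and 2014 lower in MIA_Acu). If no gene differed, 949 would be expected on average, but genes vary together and counts spread widely around that. Other splits of the 8 libraries gave 245 to 4259 such genes, so chance is not excluded for this count. On the same libraries limma voom called 0, DESeq2 1753 (841 higher and 912 lower) and voom with sample weights 2249. In the 6 libraries numbered 1, 2 and 5, edgeR called 1963 of 18941 genes, of which 1179 rose and 784 fell. This difference depended on the MIA library numbered 4: without it alone, 1340 genes passed (677 higher and 663 lower). With MIA 4 left out, 0 genes passed when MIA_Acu 2 or MIA_Acu 5 was left out too, so the calls rest on these 2 libraries as well. The genes named below with an adjusted p of the 6 libraries therefore hold for those libraries.

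The 6 smallest p-values among genes higher in MIA_Acu were those of Tinagl1, Ly6c1, Cldn5, Tbx1, Klhl23 and Elk4, none past the threshold in 8 libraries (adjusted p = 0.0881 for each). Tinagl1 (ENSMUSG00000028776), a matrix protein of vessel walls, was at 11.7 ± 1.02 CPM in MIA and 20.8 ± 1.78 CPM in MIA_Acu (SD, n = 4). Cldn5 (ENSMUSG00000041378), the tight junction protein of endothelium, was at 30.4 ± 4.26 and 50.6 ± 3.05 CPM, and Ly6c1 (ENSMUSG00000079018), a surface protein of capillary endothelium, at 23.4 ± 1.62 and 37.6 ± 3.86 CPM. The transcription factor gene Tbx1 (ENSMUSG00000009097) was at 1.19 ± 0.387 and 4.38 ± 0.694 CPM, a log2 fold change of 1.88 (SE 0.27). Klhl23 had a log2 fold change of 0.67 (SE 0.11) and Elk4, a partner of serum response factor, of 0.42 (SE 0.07). In the 6 libraries all 6 of these genes rose, with adjusted p between 0.0185 and 0.0276.

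On the lower side, Sprr1a (ENSMUSG00000050359), a gene switched on in axotomised sensory neurons, was at 6.88 ± 4.04 CPM in MIA and 0.141 ± 0.178 CPM in MIA_Acu (SD, n = 4). Its counts were 98, 167, 453 and 334 in the MIA libraries and 13, 0, 0 and 7 in the MIA_Acu libraries, a log2 fold change of -5.59 (SE 0.84, adjusted p = 0.0881). Asic3 (ENSMUSG00000038276), an acid-sensing channel of muscle and joint afferents, was at 69.7 ± 8.3 and 46.2 ± 2.88 CPM. Pappa2 (ENSMUSG00000073530), a protease of insulin-like growth factor binding proteins, was at 16.4 ± 1.63 and 8.03 ± 1.22 CPM. Erich3, Csmd1 and Dock3 had log2 fold changes of -0.54 (SE 0.08), -0.44 (SE 0.07) and -0.52 (SE 0.08). Adjusted p was 0.0881 for each of these genes in 8 libraries, and in the 6 libraries each fell, with adjusted p of 0.0185 to 0.0188. With no filter on low counts, 6 genes passed in 8 libraries: Sprr1a, Tinagl1, Pappa2, Cldn5, Tbx1 and Ly6c1.

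**Figure D1:**
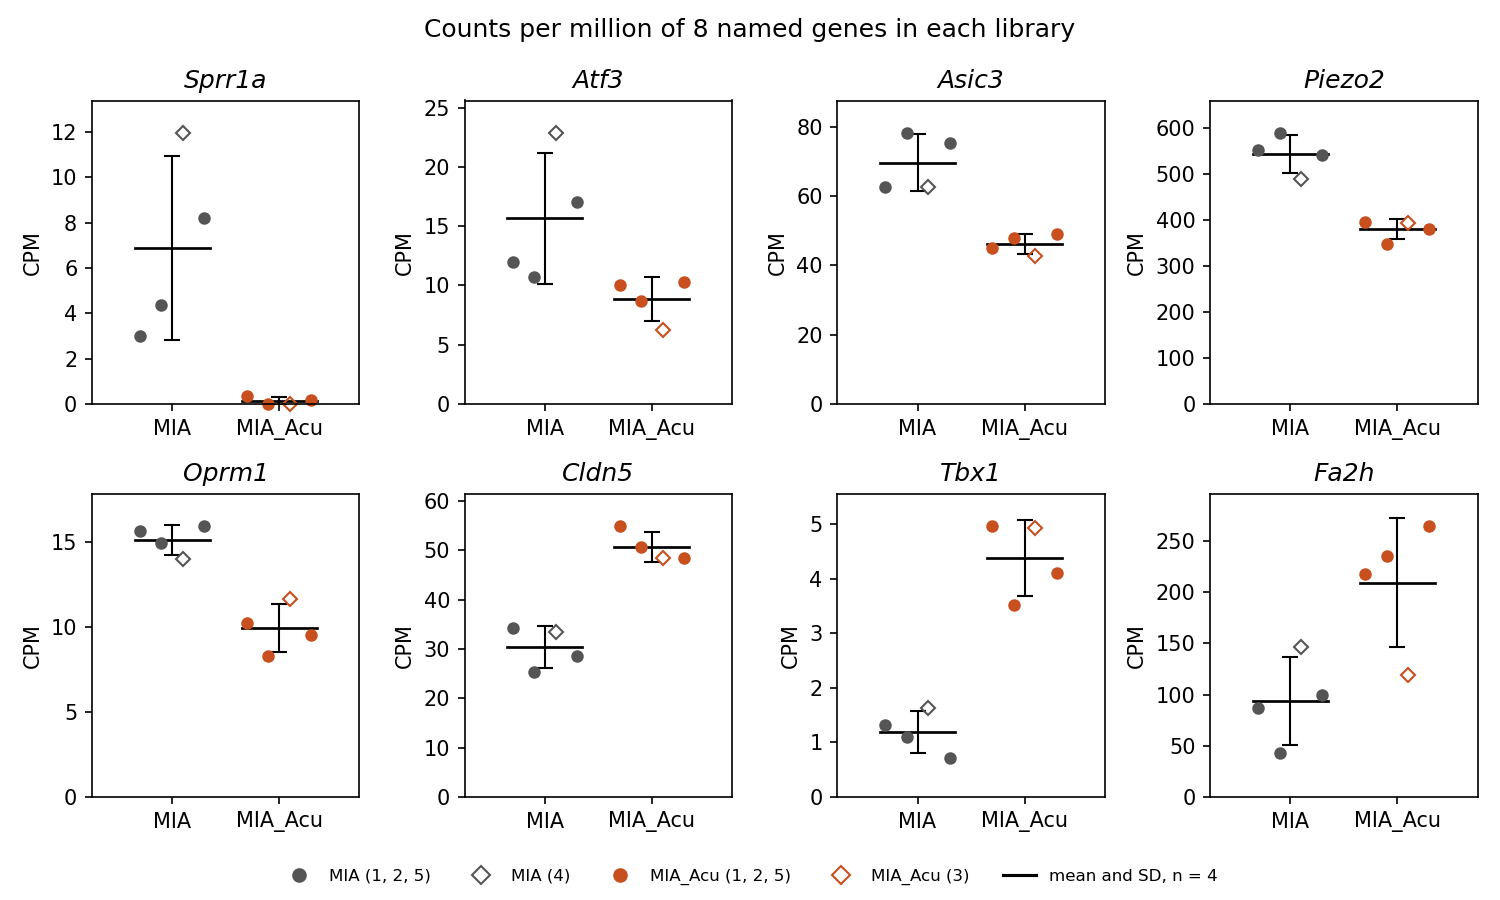
TMM-scaled CPM (linear axis) of 8 named genes in each library of the MIA and MIA_Acu groups; bars show mean and SD (n = 4), and open diamonds the MIA library numbered 4 and the MIA_Acu library numbered 3. Sprr1a lay at 2.98 to 12 CPM in MIA and at 0 to 0.371 CPM in MIA_Acu, while Fa2h of the library numbered 4 in MIA lay above that of the library numbered 3 in MIA_Acu.

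Markers of the neurons fell as a list. All 14 members of the pan-neuronal list were lower in MIA_Acu, with a median log2 fold change of -0.34 (adjusted p = 1.16e-07), and 13 passed when adjusted over the list alone, against 0 over all genes. Avil (advillin) was at 689 ± 76.5 CPM in MIA and 493 ± 58.6 CPM in MIA_Acu (SD, n = 4), and Rbfox3, which encodes NeuN, at 170 ± 18.7 and 131 ± 13 CPM. Across neuron types the medians were -0.31 for non-peptidergic nociceptors (13 of 14 members lower), -0.28 for large-diameter afferents (9 of 11), -0.33 for cold and low-threshold C afferents (6 of 8) and -0.20 for peptidergic nociceptors (10 of 10). Adjusted over the list alone, 0, 4, 2 and 1 of their members passed. Ntrk3, the neurotrophin-3 receptor of large afferents, was at 410 ± 27.2 and 270 ± 43.3 CPM. Cntnap2 had a log2 fold change of -0.49 (SE 0.08), the cold channel gene Trpm8 of -0.44 (SE 0.10), Cdh8 of -0.38 (SE 0.11), Ret of -0.41 (SE 0.14), Mrgprx1 of -0.32 (SE 0.10) and Gfra3 of -0.31 (SE 0.11). With an estimated correlation, adjusted p of these 5 lists lay between 0.413 and 0.549. The peptidergic nociceptor call ended without the MIA library numbered 1 (adjusted p = 0.0607) or the MIA_Acu library numbered 5 (0.0641). That of C-LTMR and cold ended without MIA 1 (0.0651), MIA_Acu 3 (0.0735) or MIA_Acu 5 (0.0546), and with the libraries numbered 3 and 4 exchanged (0.215).

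Ion channels of nociception fell by a median of 0.373 on the log2 scale (29 of 31 members lower, adjusted p = 6.99e-10). Adjusted over the list alone 16 members passed, and in the 6 libraries 16 of 31 fell over all genes tested and 15 did not pass. Piezo2, the mechanotransduction channel of touch and proprioception, was at 544 ± 41.4 CPM in MIA and 380 ± 22 CPM in MIA_Acu (SD, n = 4, adjusted p = 0.0881, 6-library adjusted p = 0.0185). Scn10a, the sodium channel Nav1.8 of nociceptors, was at 912 ± 118 and 662 ± 97.4 CPM (adjusted p = 0.112, 6-library adjusted p = 0.0317). Trpv1, the capsaicin receptor, was at 124 ± 22.5 and 106 ± 30.6 CPM, a log2 fold change of -0.23 in 8 libraries (adjusted p = 0.518) and of -0.56 in the 6 (adjusted p = 0.0201), with MIA_Acu 3 at 151 CPM above each MIA library. Synaptic vesicle release genes fell by a median of 0.337, with all 19 members lower and 15 past the threshold adjusted over the list alone (adjusted p = 6.99e-10). Syn1 had a log2 fold change of -0.45 (SE 0.09). With an estimated correlation both lists had an adjusted p of 0.413. The neurotrophic factors list had a median of -0.22 (12 of 14 lower, adjusted p = 0.0308, with an estimated correlation adjusted p = 0.413), and 5 members passed when adjusted over the list alone. It is made up mostly of receptors. The neurotrophic factors call ended without MIA 4 (adjusted p = 0.0518), MIA 5 (0.0549) or MIA_Acu 3 (0.0735), in the 6 libraries (0.0969), with no filter (0.177) and with the exchange (0.375).

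Genes of the nerve injury response fell as a list (median log2 fold change -0.21, 15 of 23 members lower, adjusted p = 0.00148, and with an estimated correlation adjusted p = 0.413). Adjusted over the list alone 9 members passed, against 0 over all genes. Atf3, the transcription factor of injured neurons, was at 15.7 ± 5.53 CPM in MIA and 8.84 ± 1.86 CPM in MIA_Acu (SD, n = 4, adjusted p = 0.125, 6-library adjusted p = 0.15), and Serpina3n at 155 ± 9.54 and 119 ± 11.1 CPM (adjusted p = 0.0881, 6-library adjusted p = 0.028). Chosen after their values were seen, Sox11 was at 12.9 ± 0.78 and 8.96 ± 1.1 CPM, the neuropeptide gene Nts at 13.6 ± 3.72 and 6.04 ± 2.23 CPM, and Ecel1 at 2.82 ± 1.49 and 0.979 ± 0.351 CPM, with adjusted p of 0.0881, 0.0906 and 0.103. Their 6-library adjusted p were 0.0548, 0.0831 and 0.116, none past the threshold. Galanin (Gal) was at 9.45 ± 1.89 and 6.73 ± 2.6 CPM (adjusted p = 0.29, 6-library adjusted p = 0.0248). The injury score was 0.08 to 0.61 in the MIA libraries and -0.48 to -0.19 in the MIA_Acu libraries, a difference of -0.60 (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). This p is unadjusted, and the list was picked for the test after the results were seen. Scores of the ion channel, endothelial, mural, fibroblast, extracellular matrix, NF-kB and TLR, immediate early and glucocorticoid lists did not overlap between groups either. The p is therefore not particular to the injury list and does not exclude chance over 48 lists. The 8 members higher in MIA_Acu include Fst with a log2 fold change of 0.37 (adjusted p = 0.394), Socs3 of 0.33 (0.4) and Klf6 of 0.22 (0.227). In the 6 libraries 3 members of the list fell, 1 rose (Fst, log2 fold change 0.72, adjusted p = 0.028) and 19 did not pass. The call of the nerve injury response ended with the libraries numbered 3 and 4 exchanged (adjusted p = 0.817).

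**Figure D2:**
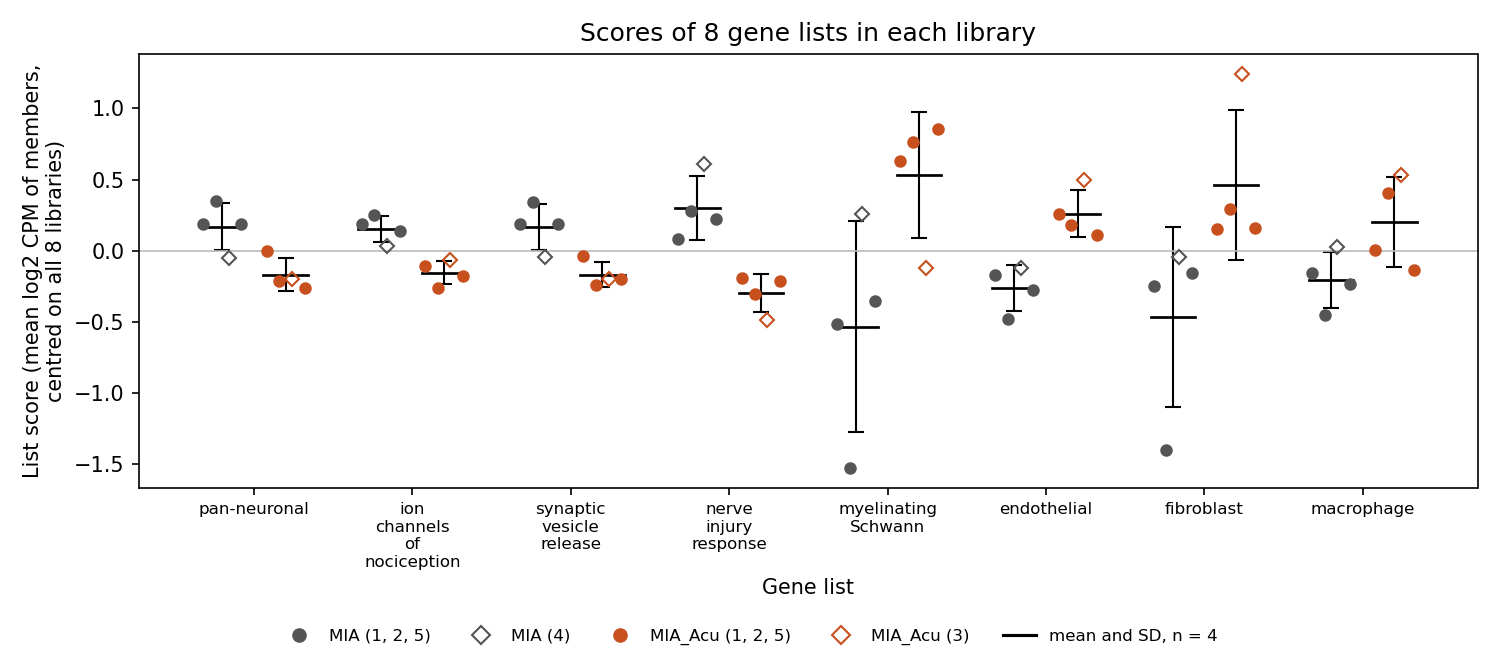
Scores of 8 gene lists (vertical axis, mean log2 CPM of the members centred on all 8 libraries) in each library of the MIA and MIA_Acu groups; bars show mean and SD (n = 4), and open diamonds the MIA library numbered 4 and the MIA_Acu library numbered 3. Scores of the groups do not overlap for the nerve injury response, ion channel, endothelial and fibroblast lists. The myelinating Schwann score of MIA 4 (0.26) lies above that of MIA_Acu 3 (-0.12).

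The myelinating Schwann list rose, with 15 of 15 members higher in MIA_Acu and a median log2 fold change of 1.005 (adjusted p = 3.95e-07, with an estimated correlation adjusted p = 0.474). Adjusted over the list alone 14 members passed, and in the 6 libraries all 15 rose over all genes tested, with a median of 1.45. Fa2h, an enzyme of myelin lipid synthesis, was at 94.2 ± 42.9 CPM in MIA and 209 ± 62.9 CPM in MIA_Acu (SD, n = 4, adjusted p = 0.125, 6-library adjusted p = 0.0187). Pmp2, Ugt8a and Fa2h rose in the 6 libraries by log2 fold changes of 1.85, 1.80 and 1.64, against 1.20, 1.25 and 1.15 in 8. The highest myelinating Schwann scores, 0.86 in MIA_Acu 5 and 0.76 in MIA_Acu 2, were in the libraries with the highest spinal cord scores (3.11 and 2.01). MIA_Acu 1, next at 0.63, had a low spinal cord score (-1.61). The satellite glia list was not called in 8 libraries (median 0.15, adjusted p = 0.159), but was called higher in the 6 (median 0.224, adjusted p = 0.0433, with an estimated correlation adjusted p = 0.581). That of non-myelinating and repair Schwann cells was not called in 8 libraries (adjusted p = 0.295), and its median of 0.06 and test direction (lower) differ in sign.

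Endothelial markers rose by a median of 0.53 (10 of 10 members higher, adjusted p = 3.03e-07) and mural markers by 0.48 (9 of 9, adjusted p = 0.0012), with an estimated correlation adjusted p = 0.413 for both. Adjusted over the list alone 10 and 4 members passed. Pdgfrb, a receptor of pericytes, was at 51.1 ± 9.53 CPM in MIA and 71.2 ± 3.45 CPM in MIA_Acu (SD, n = 4), and Kcnj8 at 2.62 ± 0.591 and 5.39 ± 1.89 CPM. Fibroblast markers (12 of 12 higher, median 0.93, adjusted p = 0.000369) and extracellular matrix and fibrosis genes (25 of 26 higher, median 0.86, adjusted p = 1.89e-06) rose too, each with an estimated correlation at adjusted p = 0.474. Of these lists 5 and 11 members passed when adjusted over the list alone. Col1a2 was at 457 ± 182 and 1310 ± 817 CPM, Col3a1 at 192 ± 75.3 and 405 ± 68.2 CPM, and Col5a2 at 72.6 ± 20 and 128 ± 23.2 CPM. The fibroblast score was highest in MIA_Acu 3 (1.24), the library with the highest bone and cartilage score (4.01), and lowest in MIA 2 (-1.40), that with the lowest skeletal muscle score (-5.04). Exchanging the libraries numbered 3 and 4 ended the endothelial (adjusted p = 0.132), mural (0.215), fibroblast (0.209) and extracellular matrix and fibrosis (0.126) calls.

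Of the immune lists, macrophage markers rose (17 of 18 higher, median 0.50, adjusted p = 0.000713), as did NF-kB and TLR signalling (19 of 21, median 0.27, adjusted p = 0.000287), interferon response (32 of 34, median 0.43, adjusted p = 0.0105) and complement (15 of 17, median 0.35, adjusted p = 0.0327). With an estimated correlation their adjusted p were 0.474, 0.413, 0.748 and 0.549, and adjusted over the list alone 0 members of each passed. Macrophage scores of the groups overlapped. They were 0.531 in MIA_Acu 3, the library with the highest bone and cartilage score (4.01), and 0.408 in MIA_Acu 2. MIA_Acu 1 (0.006) and MIA_Acu 5 (-0.133) lay below MIA 4 (0.028). The macrophage marker gene Cd68 was at 3.25 ± 0.605 CPM in MIA and 6.15 ± 2.68 CPM in MIA_Acu (SD, n = 4), F13a1 at 14.4 ± 1.4 and 21.4 ± 4.77 CPM, Traf1 at 6.32 ± 1.64 and 10.4 ± 1.76 CPM, Hmgb1 at 86.3 ± 8.72 and 107 ± 9.96 CPM, and C1qa at 10.5 ± 2.5 and 15.7 ± 2.79 CPM. Cd59a, which restrains complement, had a log2 fold change of 0.34 (SE 0.16), Ifit3 of 0.77 (SE 0.26) and Bst2 of 0.63 (SE 0.25). The interferon response call rested on MIA_Acu 3 and MIA_Acu 2, ending without either (adjusted p = 0.567 and 0.101) and in the 6 libraries (0.65). The complement call ended without MIA 2 (0.167), MIA_Acu 1 (0.084) or MIA_Acu 2 (0.151), and the exchange ended those of macrophage (0.251) and NF-kB and TLR signalling (0.0561) and turned interferon response lower (median -0.25, adjusted p = 0.0528).

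Inflammatory cytokines and chemokines were not called (median 0.22, adjusted p = 0.174). Il1b was at 1.46 ± 0.315 CPM in MIA and 1.4 ± 0.933 CPM in MIA_Acu (SD, n = 4), Ccl2 at 1.71 ± 0.455 and 1.83 ± 1.17 CPM, Csf1 at 22.5 ± 3.06 and 23.8 ± 5.13 CPM, and Cx3cr1, the fractalkine receptor of macrophages, at 7.99 ± 2.37 and 11.5 ± 2.76 CPM, none past the threshold in 8 or 6 libraries. Il6 (0.175 ± 0.151 and 0.118 ± 0.0901 CPM) and Tnf (0.202 ± 0.0696 and 0.25 ± 0.0961 CPM) lay below the filter on low counts and a difference was not detectable at this depth. The transmitter genes Calca, for the peptide CGRP, and Tac1, for substance P, were at 796 ± 95.5 and 710 ± 122 CPM and at 216 ± 36.2 and 195 ± 36 CPM, neither past the threshold. Bdnf had a log2 fold change of -0.03 (SE 0.12), Penk of 0.25 (SE 0.26), Fos of 0.30 (SE 0.20) and Gfap of 1.31 (SE 1.02), also not past it. The mu opioid receptor gene Oprm1 was at 15.1 ± 0.869 and 9.92 ± 1.41 CPM (log2 fold change -0.61, SE 0.12, adjusted p = 0.0881, 6-library adjusted p = 0.0185), while the list of opioid, cannabinoid and adenosine genes was not called by camera (median -0.03, adjusted p = 0.11) and was by fry (adjusted p = 0.0491).

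Lists of response genes and of RNA classes also rose. Glucocorticoid response genes were higher in 14 of 15 members (median 0.44, adjusted p = 0.00148, with an estimated correlation adjusted p = 0.474), among them Sgk1 at 34 ± 8.92 CPM in MIA and 60.6 ± 19.8 CPM in MIA_Acu (SD, n = 4) and Errfi1 at 41.6 ± 5.3 and 56.5 ± 4.29 CPM. The glucocorticoid response score of MIA_Acu 5 (0.682) stood far above the next of its group (0.139), and Sgk1 was at 88.9 CPM in that library. Immediate early genes were higher in 17 of 23 members (median 0.30, adjusted p = 0.00747, with an estimated correlation adjusted p = 0.413). Its members with the smallest p-values were Cyr61 (7.84 ± 2.25 and 16.8 ± 2.75 CPM), known from mechanically stretched and matrix-rich tissue, and Klf2 (7.58 ± 1.29 and 13.3 ± 3.96 CPM), a flow-induced factor of endothelium. Mitochondrial mRNA was higher in 13 of 13 members (median 0.38, adjusted p = 1.25e-05) and ribosomal proteins in 47 of 48 (median 0.17, adjusted p = 5.55e-09), both at adjusted p = 0.474 with an estimated correlation. Members past the threshold adjusted over the list alone were 5 of the glucocorticoid response, 5 of the immediate early genes, 8 of mitochondrial mRNA and 0 of ribosomal proteins. The share of counts on mitochondrial genes was 3.24% to 3.39% in MIA and 3.83% to 5.44% in MIA_Acu. Scores of the mitochondrial mRNA list did overlap. MIA_Acu 5 (-0.257) lay below MIA 1 (-0.139), MIA 2 (-0.162) and MIA 4 (-0.068) and above MIA 5 (-0.383), and MIA_Acu 3 was highest (0.583). mt-Nd4 had a log2 fold change of 0.48 (SE 0.12), mt-Cytb of 0.43 (SE 0.11), Rpl18 of 0.27 (SE 0.07) and Rplp0 of 0.31 (SE 0.09). Exchanging the libraries numbered 3 and 4 ended the calls of immediate early genes (adjusted p = 0.436) and mitochondrial mRNA (0.528).

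Markers of neighbouring tissues varied widely between libraries. Skeletal muscle (12 of 12 higher, median 0.89, adjusted p = 0.0327) and adipocyte markers (7 of 7, median 1.49, adjusted p = 0.0223) rose in MIA_Acu, at adjusted p = 0.748 and 0.549 with an estimated correlation and with 0 members past the threshold adjusted over the list alone. Myh7 was at 3.18 ± 5.39 CPM in MIA and 56.3 ± 78.8 CPM in MIA_Acu (SD, n = 4), Myh2 at 46.5 ± 42.5 and 139 ± 130 CPM, Cidec at 0.373 ± 0.422 and 1.05 ± 0.562 CPM, and Pck1 at 0.343 ± 0.172 and 1.04 ± 1.2 CPM. The skeletal muscle score was -5.04 in MIA 2, which also had the lowest myelinating Schwann (-1.53) and fibroblast (-1.40) scores, and 2.45 in MIA_Acu 3. Spinal cord markers scored 3.11 in MIA_Acu 5, 2.01 in MIA_Acu 2 and 0.79 in MIA 4, and below 0 in the rest. Bone and cartilage markers scored 4.01 in MIA_Acu 3, which also had the highest fibroblast (1.24), neutrophil (1.41) and erythroid (1.08) scores. The spinal cord and the bone and cartilage lists were not called in 8 libraries (adjusted p = 0.126 for each). The spinal cord list was called higher in the 6 libraries (median 3.087, adjusted p = 0.0354, with an estimated correlation adjusted p = 0.617), and the median of bone and cartilage was -0.069. The skeletal muscle call ended without MIA 2 (adjusted p = 0.545), MIA_Acu 1 (0.084), MIA_Acu 3 (0.129) or MIA_Acu 5 (0.0993), in the 6 libraries (0.076) and with the exchange (0.251), and the adipocyte call without MIA 2 (0.109) or MIA_Acu 3 (0.101) and with the exchange (0.297).

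**Figure D3:**
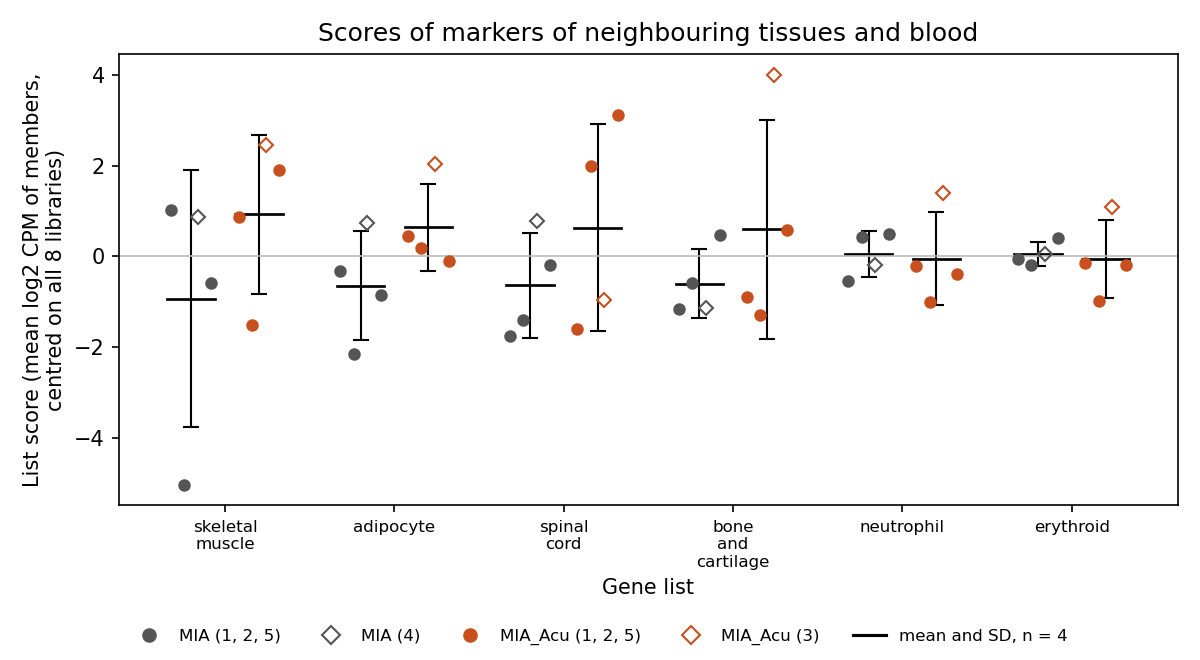
Scores of 6 lists of markers of tissues and blood cells next to the ganglion (vertical axis, mean log2 CPM of the members centred on all 8 libraries) in each library of the MIA and MIA_Acu groups; bars show mean and SD (n = 4), and open diamonds the MIA library numbered 4 and the MIA_Acu library numbered 3. The lowest skeletal muscle score, -5.04, was in MIA 2, and the highest bone and cartilage score, 4.01, in MIA_Acu 3.

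In the 6 libraries numbered 1, 2 and 5, the largest rise among named genes was that of the serotonin receptor gene Htr2c (log2 fold change 3.66, SE 0.96, adjusted p = 0.0476). Its CPM of 0.485 ± 0.364 and 3.07 ± 3.73 over all libraries (SD, n = 4) spread widely in MIA_Acu, where MIA_Acu 2 and MIA_Acu 5 also had the highest spinal cord scores. Dlk1, Atp10b, Tbx1, Erbb4, Lrtm2, Bhlhe22 and C1qtnf6 rose by log2 fold changes of 2.29, 2.04, 2.01, 1.97, 1.77, 1.73 and 1.65. Of the genes that fell, Sprr1a led (-4.78, SE 0.75), followed by Apol11b (-2.22, SE 0.43), Srd5a2, a steroid 5-alpha-reductase (-1.34, SE 0.30), Fgr, a kinase of myeloid cells (-1.13, SE 0.28), Ccdc60 (-1.07, SE 0.24), Pappa2 (-1.07, SE 0.16) and Rtl9 (-1.05, SE 0.21). Slc5a11, Lrguk, Rgs9, Gal and Ces2g fell by 0.966, 0.965, 0.928, 0.881 and 0.865. Some of these values lay closer to 0 in 8 libraries: 0.849 for Dlk1, -0.257 for Srd5a2, -0.264 for Fgr, -0.401 for Lrguk and -0.356 for Rgs9, with adjusted p of 0.5 or more. For Fgr, MIA_Acu 3 was at 6.2 CPM and the other MIA_Acu libraries at 1.2 to 2.17 CPM. Over the fixed lists, 121 of the genes passed over all genes tested and 206 adjusted over the list alone, against 0 and 122 in 8 libraries. Of the 24 lists, 21 were called in the same direction in the 6 libraries, where 28 were called in all, and 0 with an estimated correlation (smallest adjusted p = 0.57). Called only in the 6 were satellite glia, spinal cord and cholesterol synthesis, which rose, and neuropeptides, proliferation, neutrophil and erythroid, which fell.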

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

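The tests of dilution, of attached tissue, of the injury list, with and without Sprr1a, and of Sprr1a against neuron content, and both tests of the library numbered 4 were chosen after the results were seen; the splits and the length and GC test were set out before their results. Of 270 groups of 4 libraries examined for a single library far from the other 3, 17 stood out, and chance gives about 1 in 20 (14). The MIA_Acu library numbered 3 accounts for 8 of them. Its list scores were 1.24 for fibroblast (next 0.294), 1.06 for extracellular matrix and fibrosis (next 0.238) and 0.418 for inflammasome and pyroptosis (next -0.05), and its log2 CPM was 11.3 for Col1a2 (next 9.86), 1.53 for Pck1, 5.22 for Gfra3 and 5.39 for Lrguk, all above the other 3, and 6.82 for Cd59a (next 7.45), below them. The MIA library numbered 2 was lowest of its group for the fibroblast score (-1.4, next -0.25) and for the log2 CPM of Col3a1 (6.35), Cyr61 (2.2) and Fos (1.9). MIA 4 was highest for Tinagl1 (3.73) and lowest for Ccdc60 (0.757), MIA 1 was lowest for Ntrk3 (8.53), and MIA_Acu 5 was highest for the glucocorticoid response score (0.682, next 0.139) and lowest for Tnf (-2.61).

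Neuronal lists were lower and myelin, vessel and matrix lists higher in MIA_Acu. A bias by transcript length or GC is argued against as the whole cause, since 11 of the 12 lists of this pattern stayed called with each library's trend removed. If all cells other than neurons had diluted them alike, the myelinating Schwann score would rise no more than that of satellite glia; it rose by 0.886 more (exact permutation test, two-sided, p = 0.0571), which leaves dilution open. If more nerve, root or connective tissue had been taken with the ganglia, libraries of a group with more of these markers would hold fewer neuronal transcripts: the group-centred Pearson correlation was -0.765 (permutation p = 0.0781) and Spearman's rho -0.595 (p = 0.163) over 8 libraries, while r was -0.9 among the 4 MIA libraries, -0.402 among the 4 MIA_Acu libraries and -0.194 without MIA 2 and MIA 4. Dissection, dilution and an effect of acupuncture, or of the handling that goes with it, cannot be told apart here. Of the 35 splits of the 8 libraries, 5, the real one included, called at least as many lists (24 in the real one, 26 in the highest other). Chance is therefore not excluded for the number of lists.

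Nerve injury genes were lower in MIA_Acu, Sprr1a most of all. For Sprr1a, a loss of neurons from the libraries is argued against: the upper bound of the 95% interval of its log2 fold change was -3.71, below the lowest change of a pan-neuronal member (-0.48). For the list, the injury score less the pan-neuronal score differed by -0.259 (exact permutation test, two-sided, p = 0.229), and without Sprr1a by -0.036 (p = 0.914), while the injury score without Sprr1a differed by -0.374 (p = 0.0286). A lower neuron content therefore stays open for the other 22 members as a set. A weaker injury response after acupuncture, or joint injections that damaged nerve to a different degree, remain as hypotheses that these libraries do not separate.

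The number of genes past the threshold rested on the MIA library numbered 4 and, with that library left out, on MIA_Acu 2 and MIA_Acu 5. On the 1961 tested genes called in the other 6 libraries, MIA 4 lay at a median of 0.637 of the way from the MIA mean to the MIA_Acu mean and the MIA_Acu library numbered 3 at 0.632. By the median both thus lay nearer to the MIA_Acu mean, MIA_Acu 3 with its own group and MIA 4 with the other. The genes were chosen, and the positions scaled, on the other 6 libraries, which pulls libraries outside that fit toward the middle. How far each lay from a mean therefore decides nothing. Of these genes, MIA 4 alone lay nearer to the other group on 851, both did on 549, MIA_Acu 3 alone on 189 and neither on 372, Sprr1a among the last (453 and 0 counts). An exchange would put both nearer to the other group, which the median of MIA_Acu 3 and the largest class do not show. As the genes go both ways, however, an exchange of the 2 cannot be told apart from libraries of mixed content or from that pull toward the middle. On the injury list each is the most extreme of its own group (0.61 and -0.48), and on the mitochondrial share each lies with its own group (3.39% and 5.44%). More attached nerve or root in MIA 4 is a candidate explanation: its myelinating Schwann score exceeds the highest of the other 3 MIA libraries by 0.61, and its pan-neuronal score lies 0.24 below their lowest. The genes called in the other 6 libraries include myelin and neuronal genes, so these scores partly restate the position of MIA 4. An exchange would give the same scores, so they do not decide between the 2 explanations.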

How the results depend on the processing

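The exchange of the libraries numbered 3 and 4, the omission of pairs and the length and GC correction were added after the data were examined. Against 0 genes in 8 libraries, 6 passed with no filter, 1963 in the 6 libraries numbered 1, 2 and 5, 1753 with DESeq2 (4806 genes with no adjusted p), 2249 with voom and sample weights, 207 with the exchange, 4137 at an unadjusted p under 0.05, and 0 to 1340 with each library left out, where only omission of MIA 4 gave any. Of 16 omitted pairs, only MIA 4 with MIA_Acu 1 (1941) and with MIA_Acu 3 (1963) gave any. DESeq2 size factors, the stricter filter and voom gave 0, and with those size factors all 107 named genes and called lists kept their direction and side of the threshold. The 6-library and DESeq2 calls shared 1183 genes. Genes past the threshold adjusted over the list alone went from 122 to 206 in the 6 libraries, 216 with voom and sample weights, and 69 to 192 with each library left out. Of the 24 lists called, 0 were called with an estimated correlation and 5 with fry, which also called opioid, cannabinoid and adenosine (adjusted p = 0.0491), 6 in all; on ranks and with DESeq2 size factors all 24 kept direction and call, and with the length and GC trend removed 23 did, C-LTMR and cold being the exception (adjusted p = 0.0569). Its median was -0.391 (SD of members 0.252) after removal and -0.329 (SD 0.257) before, so the call did not end through a smaller change, and what ended it was not tested. With the replicate number as a block on the 6 libraries, 1486 genes passed (1014 higher and 472 lower, against 1179 and 784 without the block), and 223 adjusted over the list alone. What the numbers share is not given: deviations of same-numbered libraries from their group means correlated at 0.062, 0.265 and 0.02, and only the libraries numbered 2 were each other's best match. The block turned Csf1 (-0.006) and Penk (-0.091), as the 6 libraries did without it (-0.009 and -0.117).

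Other log2 fold changes that turned were Ccl2 with voom (-0.119) and with sample weights (-0.136), Csf1 with sample weights (0.00), and, with the exchange, Cd68 (-0.022), Col1a2 (-0.167), Myh7 (-1.807), Myh2 (-0.348), Pck1 (-1.147), Csf1 (-0.082), Atf3 (0.176), Penk (-0.413) and the interferon response (median -0.246). With each library left out, the ranges that crossed 0 were -1.199 to 0.048 for Srd5a2, -0.564 to 0.225 for Il1b, -0.129 to 0.025 for Bdnf, -0.376 to 0.33 for Ccl2, -0.083 to 0.171 for Csf1 and -0.009 to 0.411 for Penk. None of these genes passed the threshold in 8 libraries. Depth limits Il6 and Tnf, which lay under 1 CPM.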

Other observations

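Of 19 genes of the opioid, cannabinoid and adenosine list tested in the 6 libraries numbered 1, 2 and 5, 3 fell, each a receptor gene: Oprm1, Oprd1 and Cnr1. The median of the pan-neuronal list was -0.335 in 8 libraries and -0.403 in the 6, against -0.607 and -0.736 for Oprm1, -0.617 and -0.634 for Oprd1 and -0.324 and -0.503 for Cnr1. Oprm1 and Oprd1 fell further than each pan-neuronal member (lowest -0.483 and -0.548, Avil), Cnr1 did not, and no test set these genes against the neuronal markers. Chosen, like Cnr1, after its values were seen, the delta opioid receptor gene Oprd1 was at 14 ± 1.36 CPM in MIA and 9.14 ± 0.713 CPM in MIA_Acu (SD, n = 4, adjusted p = 0.0881, 6-library adjusted p = 0.0234), close to the log2 fold change of Oprm1 (-0.62 and -0.61), and the cannabinoid receptor gene Cnr1 was at 44.4 ± 4.73 and 35.4 ± 5.44 CPM (adjusted p = 0.164, 6-library adjusted p = 0.0188). Log2 fold changes of Oprk1 and of the precursor genes Penk, Pdyn and Pomc were -0.02 (SE 0.29), 0.25 (SE 0.26), 0.15 (SE 0.85) and 0.10 (SE 0.38) in 8 libraries and -0.244, -0.117, 1.04 and -0.066 in the 6, none past the threshold, and Pdyn and Pomc lay under 1 CPM. Cholesterol synthesis genes, which myelin growth uses, were not called in 8 libraries (median -0.004, test direction higher, adjusted p = 0.69), but in the 6 libraries the list rose (adjusted p = 0.0274, with an estimated correlation adjusted p = 0.602), with 8 of 20 members past the threshold and higher.

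The other lists were not called in 8 libraries. Medians of the log2 fold change were -0.15 for neuropeptides (adjusted p = 0.113), 0.05 for neuropeptide receptors (0.964, test direction lower), 0.25 for anti-inflammatory and resolution genes (0.126), 0.12 for immune receptors on sensory ganglia (0.399), 0.10 for inflammasome and pyroptosis (0.733), 0.07 for MHC class I (0.733) and 0.30 for MHC class II (0.126). They were -0.14 for heat shock (0.126), 0.18 for circadian clock (0.135), 0.03 for nuclear OXPHOS (0.562) and 0.25 for proliferation (0.671). Of the blood and immune cell lists, neutrophil had a median of 0.05 (0.671, test direction lower), T and NK cell -0.14 (0.515), B and plasma cell 0.26 (0.964), mast cell -0.04 (0.69) and erythroid 0.06 (0.733, test direction lower), and the meningeal list one of 0.11 (0.344). Of these lists 4 were called lower in the 6 libraries: neutrophil (median -0.696, adjusted p = 0.00378), neuropeptides (-0.335, 0.0386), proliferation (-0.399, 0.0427) and erythroid (-0.646, 0.0456), with adjusted p of 0.602 to 0.617 with an estimated correlation. The medians of neutrophil, proliferation and erythroid thus changed sign.

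Splits of the libraries without regard to group were used to ask whether chance is excluded. It is not for the 8 libraries: 2 of 35 splits, the real one included, gave as many genes at an unadjusted p under 0.05 (4137 in the real one, 4259 in the highest other). At an adjusted p under 0.05 the real split gave 0 genes, which no split can lie below, so that count decides nothing. The highest other gave 236, with MIA 4 and MIA_Acu 1 changing sides, and the exchange of the libraries numbered 3 and 4 gave 207. Both keep 3 libraries of each group together and move MIA 4. The 6 libraries numbered 1, 2 and 5 have 10 splits, too few for a share under 0.05: the real one gave 1963 genes, the highest other gave 1, and the number of splits with as many as the real one, itself included, was 1.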
